A study of Mus musculus with 4 samples.

How the data were processed

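Kidney cells of 4 groups of mice with anti-GBM serum nephritis (vehicle, panobinostat, givinostat and ruxolitinib) were measured by droplet single-cell RNA sequencing, 1 library per group. The deposited matrix holds UMI counts per gene and cell, with no normalization, made with Cell Ranger 3.0.1 and genome build mm10 per the submitters' processing notes, which state no filter on cells or genes. Whole numbers and unequal cell totals in the matrix were checked. Each cell's name carries a library name, and 3 of these match the drug of 1 sample; the remaining one was taken as the vehicle library, since it is the only group without a drug. Gene symbols were matched to GENCODE vM21, and 16519 of 16706 were found there. Coordinates are those of GRCm38 (mm10).

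Cells with at least 200 genes, at least 500 UMIs and under 50% mitochondrial UMIs were kept, which left out 226 cells, all under 200 genes. The highest mitochondrial shares were 39.96%, 39.97%, 39.98% and 39.98% (vehicle, panobinostat, givinostat and ruxolitinib), and no cell was under 500 UMIs. Those limits therefore removed no cell. The near-equal highest shares point to a cell filter before deposit, which the notes do not state. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1.0 without batch integration (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15, numpy 2.4.6, scipy 1.17.1). A cluster was named for the class of fixed markers that led it. It stayed unnamed with fewer than 3 markers over 1 log2 unit above their median over clusters, or with a median doublet score above 0.2. It also stayed unnamed with a lead under 0.5 over the next class, unless its 10 top genes held a marker of its own class and no more markers of other classes. A cluster with no own marker there also stayed unnamed if its median UMI count was under 1/3 of the library median. Dendritic-like cluster 7, with a lead of 0.206, was named by its own marker Cd209a, and cluster 26, with 0.281, had none. Cluster 7 holds 643 of 1009 dendritic-like cells. With the stricter cell filter the matching cluster of 608 cells stayed unnamed, closest to macrophages with a lead of 0.0500. These thresholds were set after the data were seen. Named cells are called X-like, since no protein or position was measured.

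Counts were summed per library and class or cluster where each compared library had at least 50 cells, and given as UMIs scaled to a common total (CPM). Ratios to vehicle carry exact 95% intervals from the conditional binomial, levels exact Poisson intervals and shares exact Clopper-Pearson intervals. All intervals cover counting error only: there is 1 library per group, so no test, p-value or count of changed genes was made. Log2 ratios used a pseudocount of 5 CPM. For each of 18 gene lists the median log2 ratio of members with at least 10 CPM in either library was taken, with an interval from 1000 Poisson redraws and its percentile among 10000 random lists matched on expression in 10 bins. The lists are interferon response, JAK-STAT feedback and STAT3 targets, MHC class I, MHC class II, genes known to rise with HDAC (histone deacetylase) inhibition, histone deacetylases, tubular injury, proximal tubule transport, fatty acid oxidation, extracellular matrix and fibrosis, cytokines and chemokines, proliferation, dissociation stress and immediate early, podocyte differentiation, parietal and progenitor, oxidative stress response, apoptosis and p53, and glucose and urea markers of proximal segments. Lists, filters, markers and comparisons were fixed before the data were examined.

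Genes were named by a fixed rule: per drug, in proximal tubule-like cells and in macrophage-like plus monocyte-like cells, the 6 highest and 6 lowest log2 ratios among genes with at least 100 CPM in 1 of the compared libraries, without mitochondrial, ribosomal protein, predicted, immunoglobulin, haemoglobin and sex-linked genes and markers of other classes, plus the 2 to 4 members of each described list with the highest mean CPM. Some genes that the rule names are not reported here. Genes outside the rule are named as chosen after their values were seen. The genes that separate the libraries in pairs were found by a rule set after the data were seen, at 20 CPM or more in at least 5 classes.

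Alternatives were a stricter cell filter (500 genes, 1000 UMIs, 20% mitochondrial), Leiden resolutions of 0.5 and 1.5, classes called cell by cell, Scrublet doublets left out, TMM totals (edgeR 4.0.16) and DESeq2 1.42.0 size factors (R 4.3.3), pseudocounts of 1 and 20 CPM, no member filter or 50 CPM, and cells thinned to 1 UMI number. Scrublet called 0.0255%, 0.0682%, 2.30% and 0.302% of cells in the vehicle, panobinostat, givinostat and ruxolitinib libraries. The gene ratio intervals were tested on simulated data in which 200 of 16706 genes were changed by known folds. In proximal tubule-like cells 48, 49, 46 and 47 of 50 intervals held the true ratios for folds of 0.25, 0.5, 2 and 4. True ratios were taken after rescaling to a common total, and 95.3% of unchanged genes' intervals held theirs. The simulated counts were Poisson draws from the summed counts, without spread between cells or animals. They check the calculation and not whether the intervals cover such spread.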

Results

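Total kidney cells of male C57Bl/6 mice that carry an inducible Pax2 driver with the multicolour Confetti reporter were profiled by droplet single-cell RNA sequencing. All animals received serum against the glomerular basement membrane (anti-GBM), a model of crescentic glomerulonephritis, and were sacrificed on day 7. From day 1 the groups received vehicle, panobinostat at 15 mg/kg, givinostat at 10 mg/kg (both inhibitors of histone deacetylases) or ruxolitinib at 60 mg/kg (an inhibitor of the Janus kinases JAK1 and JAK2). The labels give 2 animals per group and 1 library per group, and do not say whether each library pools both animals. The comparisons below set each drug library beside the vehicle library, and panobinostat beside givinostat, to describe which cells and genes differed under each compound. With 1 library per group there is no replicate check: intervals cover counting error only, and a difference is between libraries, not shown to be between treatments. All drug ratios share the vehicle library. A shift seen in the same direction in every drug library can therefore also come from the vehicle library alone, and is not a repeated result. The vehicle library is the one whose name in the data carries no drug, and no label uses that name.

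After filtering 15777 cells were kept: 3930 (vehicle), 4396 (panobinostat), 3472 (givinostat) and 3979 (ruxolitinib). Their UMI (unique molecular identifier) totals were 40627826 (vehicle), 36861583 (panobinostat), 45075309 (givinostat) and 42882138 (ruxolitinib). The lowest UMI count of any cell differed between libraries, at 3723 (vehicle), 2920 (panobinostat), 5272 (givinostat) and 3817 (ruxolitinib). The median was 7958 (vehicle), 6444 (panobinostat), 10019 (givinostat) and 8180 (ruxolitinib). The median mitochondrial share was 11.4% (vehicle), 12.1% (panobinostat), 6.32% (givinostat) and 8.81% (ruxolitinib). Clustering gave 36 clusters, of which 34 were named from fixed markers. They were led by proximal tubule-like cells, other tubule-like cells, and T-like, dendritic-like, macrophage-like, monocyte-like, NK-like and B or plasma-like leukocytes. No cluster met the markers of parietal epithelial cells, the cells that line the glomerular capsule. The podocyte-like cluster held 15, 5, 13 and 14 cells in the same order of libraries, under the 50 cells required for gene levels.

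A few genes separated the libraries in pairs across most cell classes, with vehicle and panobinostat on one side and givinostat and ruxolitinib on the other. Of 6421 genes measured in at least 5 of 10 classes, 7 did so in at least 70% of their classes: Tpm3-rs7, Gm10036, Gm2000, Gm10076, Rpl9-ps6, Rpl27-ps3 and Rps12-ps3. Tpm3-rs7, a copy of the tropomyosin gene Tpm3 (chromosome 14, 113314608 to 113316754), was at 4.13, 3.96, 53.8 and 53.9 UMIs scaled to a common total (CPM) in the vehicle, panobinostat, givinostat and ruxolitinib libraries. Gm10036 was at 31.7, 24.5, 6.26 and 6.44 CPM. The other pairings of libraries gave 1 gene, Rnaset2b, and 0 genes. The givinostat and ruxolitinib comparisons with vehicle therefore cross this split and the panobinostat comparison does not.

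**Figure D1:**
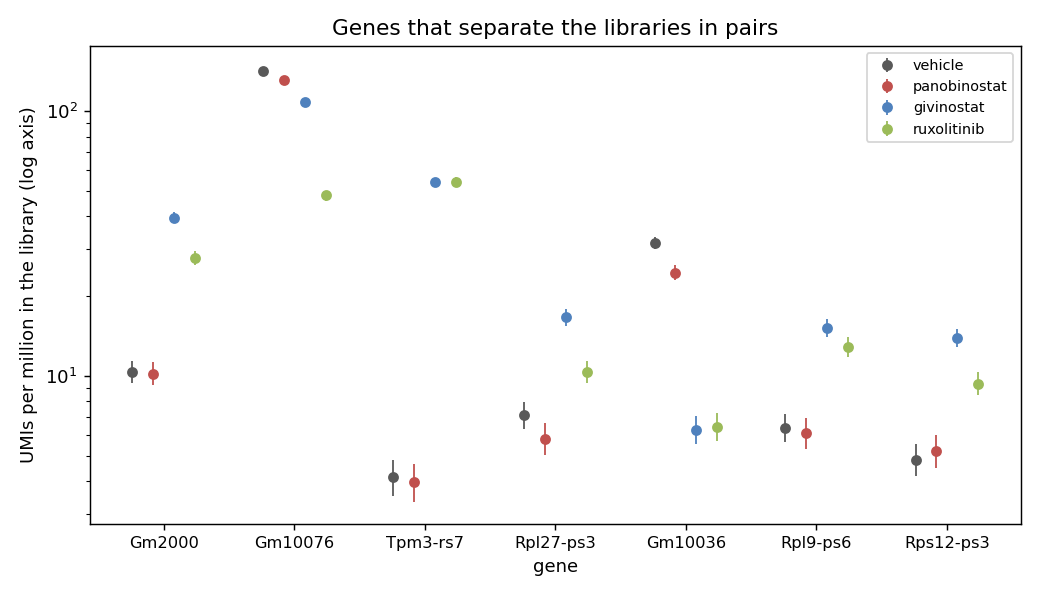
CPM (log axis) of the 7 genes that separate the libraries in pairs, 1 point per library with exact Poisson 95% intervals. Tpm3-rs7 lies low in the vehicle and panobinostat libraries (4.13 and 3.96) and high in the others (53.8 and 53.9).

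Proximal tubule-like cells, the reabsorbing epithelium of the nephron, made up 45.8% [44.2 to 47.3] of kept cells in the vehicle library, 57.4% [55.9 to 58.8] in the panobinostat library, 34.6% [33.0 to 36.2] in the givinostat library and 44.2% [42.6 to 45.7] in the ruxolitinib library (exact Clopper-Pearson 95% intervals). Cells of the collecting duct principal or connecting tubule-like class, which carry the water channel Aqp2, were 3.46% of the vehicle library and 1.46%, 1.32% and 1.83% of the panobinostat, givinostat and ruxolitinib libraries. Loop of Henle-like cells were 6.49%, 3.80%, 5.44% and 7.34% in the vehicle, panobinostat, givinostat and ruxolitinib libraries. All leukocyte-like cells together were at 0.792 [0.734 to 0.855], 1.32 [1.23 to 1.42] and 0.9993 [0.929 to 1.07] times their vehicle share in the panobinostat, givinostat and ruxolitinib libraries. Shares depend on which cells are kept, and the lowest UMI counts differ between libraries. With every library held to the highest of them 6 of 15 followed share ratios stayed within their intervals. With every library held to the same fraction of its own proximal tubule-like median 15 of 15 did. The floors already stood at 0.381, 0.380, 0.408 and 0.368 of those medians (vehicle, panobinostat, givinostat and ruxolitinib). That setting could therefore move the ratios only little. Proximal tubule-like cells had median UMI counts of 9776 (vehicle), 7688 (panobinostat), 12923 (givinostat) and 10378 (ruxolitinib). T-like cells had 4724 (vehicle), 4188 (panobinostat), 7331 (givinostat) and 5262 (ruxolitinib).

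Among leukocytes, T-like cells were compared by cluster number. T-like cluster 14, led by Il17a, the cytokine of type 17 lymphocytes, and Trdc, the constant region of the gamma-delta T cell receptor, held 2.95% [2.44 to 3.53] of the vehicle library and 0.637% [0.424 to 0.919] of the panobinostat library, 0.216 [0.138 to 0.328] times the vehicle share. The givinostat and ruxolitinib libraries had 1.06 [0.811 to 1.39] and 0.792 [0.596 to 1.05] times the vehicle share. T-like cluster 6, led by Ctla4, Icos and Cd4, was at 0.348 [0.274 to 0.439], 1.21 [1.02 to 1.44] and 0.562 [0.456 to 0.689] times its vehicle share in the panobinostat, givinostat and ruxolitinib libraries, with 6.67% of vehicle cells. Helper and regulatory T cells were not told apart in it. Over the whole library Foxp3, a regulatory T cell gene chosen after its values were seen, was at 0.735 [0.474 to 1.13], 2.56 [1.88 to 3.53] and 0.698 [0.457 to 1.06] times vehicle. At a finer clustering most cells of cluster 6 fall into 2 parts. The Ctla4 and Cd4 part was at 0.665, 2.20 and 0.777 times vehicle, and at 0.701, 2.01 and 0.834 with a stricter cell filter. The Il17f and Il17a part, chosen after its values were seen, was at 0.0917 [0.0511 to 0.154], 0.522 [0.390 to 0.695] and 0.342 [0.246 to 0.469]. The pooled ratios therefore mix 2 kinds of cells, and with every library held to the highest UMI floor they were 0.253, 3.50 and 1.04. Monocyte-like cells were 3.79% of the vehicle library and 5.85%, 8.61% and 5.78% of the panobinostat, givinostat and ruxolitinib libraries. B or plasma-like cells numbered 20, 53, 57 and 76 in the vehicle, panobinostat, givinostat and ruxolitinib libraries. Erythroid-like cells, given under other observations, were also more numerous in each drug library, and the blood content of the samples was not measured. The haemoglobin gene Hbb-bs, chosen after its values were seen, also rose in proximal tubule-like cells. It was at 29.0, 70.9, 191 and 256 CPM there (vehicle, panobinostat, givinostat and ruxolitinib). Blood cells may therefore enter the monocyte-like and B or plasma-like shares, which was not tested. T-like cells sat close to the UMI floors, with medians of 1.27, 1.43, 1.39 and 1.38 times their library's lowest UMI count. With every library held to the highest floor the Il17a and Trdc cluster stood at 0.116, 4.99 and 2.25 (panobinostat, givinostat and ruxolitinib) times vehicle and 0.235, 1.29 and 0.887 at the same fraction of each proximal tubule-like median. Clusters 26 and 27, left unnamed by thresholds set after the data were seen, held 38, 38, 42 and 34 and 52, 32, 32 and 19 cells in the vehicle, panobinostat, givinostat and ruxolitinib libraries.

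**Figure D2:**
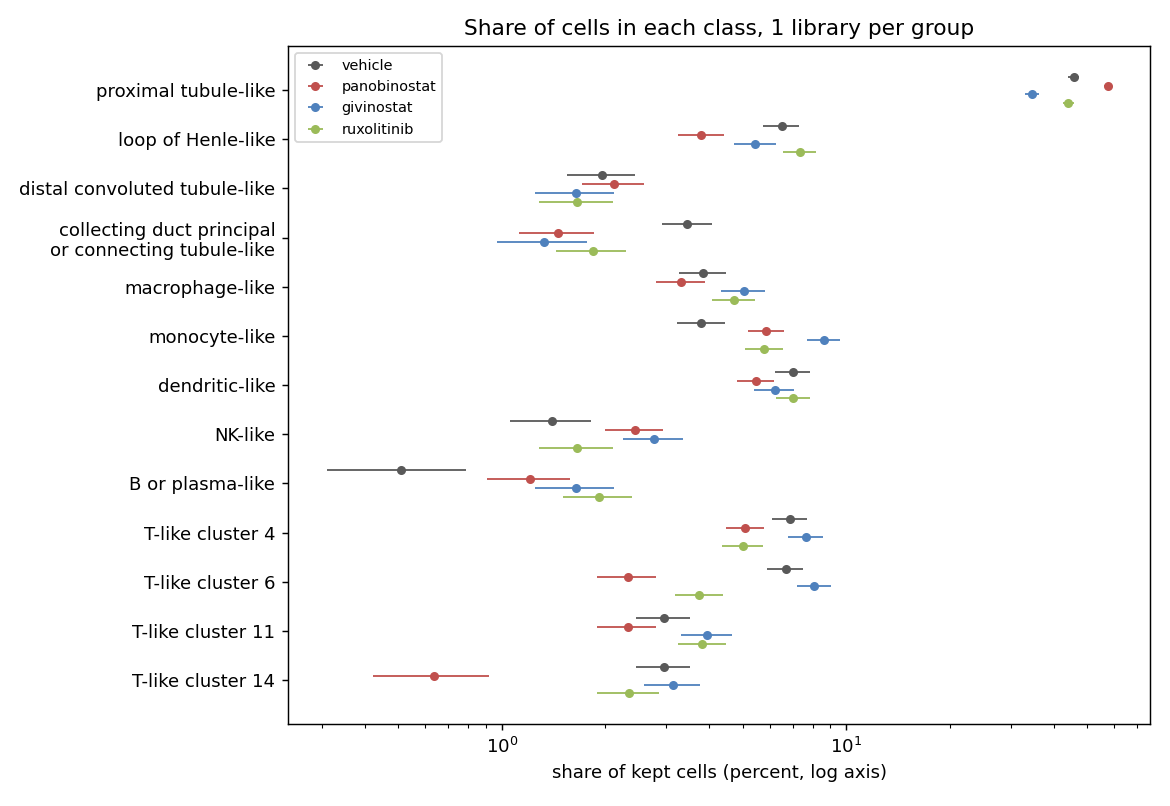
Share of kept cells in each class (percent, log axis), 1 point per library with exact Clopper-Pearson 95% intervals. In T-like cluster 14 the panobinostat point (0.637%) lies below the vehicle point (2.95%).

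In proximal tubule-like cells of the panobinostat library Lpl, lipoprotein lipase (chromosome 8, 68880491 to 68907448 of GRCm38, which is mm10), was at 129 and 306 CPM in the vehicle and panobinostat libraries, a ratio of 2.38 (95% interval 2.27 to 2.48). The glutathione transferase Gsta2, the sulfur dioxygenase Ethe1, G6pc (the catalytic subunit of glucose-6-phosphatase), the junction protein Cgnl1 and Rarres2, which encodes chemerin, were at 1.94 [1.86 to 2.02], 1.65 [1.58 to 1.73], 1.55 [1.498 to 1.60], 1.55 [1.46 to 1.65] and 1.53 [1.45 to 1.62] times vehicle. The list of glucose and urea markers had a median log2 ratio of 0.23 [0.21 to 0.24], percentile 99.8. The fatty acid oxidation list had 4 of 15 members above vehicle, at -0.09 [-0.11 to -0.04], percentile 0.62. Sgk1, a kinase controlled by steroid hormones, was at 317 and 123 CPM, 0.388 [0.371 to 0.405] times vehicle. The stress and immediate early genes Atf3, Ier2 and Zfp36, with Hbegf, an epidermal growth factor receptor ligand, were between 0.494 and 0.529 times vehicle. Angptl4, an inhibitor of lipoprotein lipase, was at 0.489 [0.468 to 0.512]. Within proximal tubule-like clusters 0, 1, 2, 3 and 5 the log2 ratio of Lpl was 1.32, 1.24, 1.29, 1.06 and 1.61, that of Sgk1 -0.09, -0.69, -1.25, 0.24 and -0.18 and that of Atf3 -0.35, -0.10, -0.64, 0.62 and 0.47. The lower pooled values of Sgk1 and Atf3 therefore lay mainly in cluster 2 and in its smaller part of these cells. Angptl4 is among the genes that mark cluster 2 and Gsta2 among those that mark cluster 3. Gatm and Ass1 of the glucose and urea list also mark cluster 3, which held 235 vehicle and 411 panobinostat cells. The median of that list is pooled over clusters, so the cluster mix may enter it.

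In proximal tubule-like cells genes that are known to rise when histone deacetylases are inhibited did not stand above vehicle as a group: 1 of 6 measured members were higher in the panobinostat library, with a median log2 ratio of -0.49 [-0.59 to -0.38], percentile 0. In macrophage-like and monocyte-like cells the list had -0.14 [-0.29 to 0.04], percentile 6.42 (panobinostat), 0.04 [-0.09 to 0.21], percentile 42.1 (givinostat) and -0.12 [-0.21 to 0.00], percentile 5.17 (ruxolitinib). Again in proximal tubule-like cells, Txnip, a thioredoxin inhibitor, was at 0.545 [0.529 to 0.561], Gadd45a, a DNA damage response gene, at 0.573 [0.534 to 0.615] and the linker histone H1f0 at 1.26 [1.18 to 1.36] times vehicle. The histone deacetylase genes themselves had a median of -0.02 [-0.09 to 0.06], percentile 36.9. The tubular injury list had a median of -0.36 [-0.45 to -0.26], percentile 0.06. With no filter on members it was -0.0587, so its size rests on the filter. Osteopontin, Spp1, was at 0.756 [0.749 to 0.765] and the keratin Krt8 at 0.625 [0.596 to 0.656] times vehicle. MHC class I genes were lower in 4 of 4 members, at -0.37 [-0.41 to -0.32], percentile 0.09. The light chain B2m was at 0.745 [0.717 to 0.774]. RNA of leukocytes was not excluded for the MHC class I genes. Transport genes such as the phosphate carrier Slc34a1, at 1.00 [0.996 to 1.01], and the receptor megalin, Lrp2, at 0.987 [0.971 to 1.00], had a median of 0.01 [-0.03 to 0.01], percentile 14.7. The stress and immediate early list had a median of -0.21 [-0.27 to -0.19], percentile 0, which moved with the mix of proximal tubule-like clusters. Cluster 2, led by Pdk4, Angptl4 and Cyr61, held 465, 406, 235 and 318 cells in the vehicle, panobinostat, givinostat and ruxolitinib libraries, and cluster 0 held 479, 819, 357 and 385. Within clusters 0, 1, 2, 3 and 5 the panobinostat medians of that list were 0.06, 0.20, -0.08, 0.39 and 0.55. In the same clusters those of the genes known to rise with deacetylase inhibition were -0.27, -0.28, -0.39, -0.15 and -0.29, and the log2 ratio of Krt8 was -0.09, -0.09, -0.54, 0.11 and 0.06.

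In macrophage-like and monocyte-like cells of the panobinostat library, Fabp5, a fatty acid binding protein, was at 0.286 [0.240 to 0.339] and the chemokine Pf4 at 0.278 [0.2199 to 0.348] times vehicle. The fungal pattern receptor Clec4n was at 0.280 [0.2201 to 0.354], the elastase Mmp12 at 0.349 [0.305 to 0.399], the mannose receptor Mrc1 at 0.462 [0.387 to 0.549] and Ms4a7 at 0.464 [0.388 to 0.552] times vehicle. The pair held 151 macrophage-like and 149 monocyte-like cells in the vehicle library and 146 and 257 in the panobinostat library. Pf4 and Ms4a7 are among the genes that mark macrophage-like cluster 8. Taken apart, the log2 ratio of Fabp5 was -2.65 in macrophage-like and -0.49 in monocyte-like cells, that of Clec4n -1.73 in macrophage-like and -1.01 in monocyte-like cells, that of Mmp12 -1.10 in macrophage-like and 0.45 in monocyte-like cells and that of Mrc1 -0.78 in macrophage-like and 0.89 in monocyte-like cells. That of Pf4 was -1.39 in macrophage-like and -0.27 in monocyte-like cells and that of Ms4a7 -0.82 in macrophage-like and 0.55 in monocyte-like cells. The MHC class II list, which presents antigen to helper T cells, had 0 of 7 members above vehicle and a median of -0.31 [-0.34 to -0.28], percentile 0.03. Cd74 was at 0.783 [0.769 to 0.797] and H2-Ab1 at 0.803 [0.783 to 0.823]. The interferon response list had a median of -0.08 [-0.18 to 0.04], percentile 11.5. The cytokine and chemokine list had -0.16 [-0.27 to -0.10], percentile 0.18, with the neutrophil attractant Cxcl2 at 0.708 [0.668 to 0.750]. The MHC class II and cytokine medians are given over both classes only, so the larger part of monocyte-like cells may enter them. The highest genes were mostly abundant transcripts of the proximal tubule: Gpx3, Ass1, Fxyd2, Igfbp7 and Spink1 were at 1.93 [1.83 to 2.04], 1.85 [1.64 to 2.10], 1.77 [1.65 to 1.92], 1.72 [1.47 to 2.03] and 1.68 [1.47 to 1.91], and the heat shock gene Hspa1b at 1.83 [1.58 to 2.14]. Gpx3 stood at 11.7% of its proximal tubule-like level in the vehicle library and 20.2% in the panobinostat library. The counts of Gpx3, Ass1, Fxyd2, Igfbp7 and Spink1 include RNA of tubule cells and were not read as leukocyte expression. Hspa1b was at 109 and 199 CPM in the vehicle and panobinostat libraries, against 24.8 and 30.1 CPM in proximal tubule-like cells. Its log2 ratio was 0.57 in macrophage-like and 2.195 in monocyte-like cells.

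In proximal tubule-like cells of the givinostat library, Cyp4a14, a fatty acid hydroxylase controlled by PPAR-alpha (chromosome 4, 115486200 to 115496142), was at 126 and 32.1 CPM in the vehicle and givinostat libraries (0.255 [0.233 to 0.279] times vehicle). The acyltransferase Mogat1, the amino acid carrier Slc7a7, the circadian factor Dbp, Tmem37 and Atf3 were at 0.539 [0.512 to 0.568], 0.577 [0.544 to 0.611], 0.532 [0.498 to 0.569], 0.501 [0.468 to 0.537] and 0.585 [0.560 to 0.610]. Higher than vehicle were the long noncoding RNA AC160336.1 (2.04 [1.95 to 2.15]; chromosome 14, 44544055 to 44637201), the integrin Itgb6 (1.84 [1.72 to 1.97]) and the organic anion carrier family member Slc22a28 (1.72 [1.63 to 1.81]). So were Ndrg1, which is induced by low oxygen (1.64 [1.61 to 1.67]), the ether lipid enzyme Agps (1.64 [1.56 to 1.73]) and the mitochondrial tRNA synthetase Lars2 (1.59 [1.54 to 1.64]). Of the genes known to rise with deacetylase inhibition, 2 of 6 measured were above vehicle, with a median of -0.28 [-0.37 to -0.20], percentile 0.05. Txnip was at 0.640 [0.622 to 0.659]. The tubular injury list had a median of -0.26 [-0.27 to -0.22], percentile 0.31. It was 0.0131 with no filter on members, a setting that draws medians toward 0. The deacetylase and injury medians are pooled over clusters, so the cluster mix may enter them. MHC class II genes had -0.35 [-0.45 to -0.25], percentile 0. Cd74 was at 194 and 125 CPM there against 10930 and 7544 CPM in macrophage-like and monocyte-like cells, so RNA of leukocytes was not excluded and the list was not read as tubule expression. The JAK-STAT feedback list had a median of 0.05 [-0.01 to 0.19], percentile 47.4, which turned to -0.0237 with TMM scaling and -0.0883 in thinned cells. The transport list had 0.09 [0.07 to 0.11], percentile 92.7. TMM and DESeq2 scaling shift the median of all genes in these cells by -0.09 and -0.11, which takes the transport median to 0.00. The stress and immediate early list had a median of -0.19 [-0.24 to -0.16], percentile 0.11, and 0.08, -0.29, 0.04, 0.01 and 0.14 within clusters 0, 1, 2, 3 and 5. There the log2 ratio of Ndrg1 was 1.11, 0.69, 0.76, 0.88 and 0.99, that of Cyp4a14 -2.45, -1.13, -1.54, 0.14 and -2.10 and that of Atf3 0.10, -0.72, -0.47, 0.61 and 0.38.

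Genes of the interferon response were higher in the givinostat library in macrophage-like and monocyte-like cells: 24 of 24 measured members were above vehicle, with a median log2 ratio of 0.66 [0.59 to 0.81], percentile 100. Ifitm3 and Bst2, which restrict viruses, were at 1.18 [1.14 to 1.22] and 1.26 [1.10 to 1.43] times vehicle, and the transcription factor Irf7 at 1.40 [1.22 to 1.62]. Both chosen after their values were seen, the chemokine Cxcl10 was at 2.60 [2.06 to 3.33] and Isg15 at 1.76 [1.46 to 2.15]. The list median was 0.77 in macrophage-like cells, 0.83 in monocyte-like cells, 0.47 in dendritic-like cells, 0.55 in NK-like cells and 0.37, 0.39, 0.29 and 0.47 in T-like clusters 4, 6, 11 and 14. Among dendritic-like cells, cluster 7, which loses its name with the stricter cell filter, had 0.59 and the other clusters 0.24. The median was 0.14 in proximal tubule-like cells and 0.00 in loop of Henle-like cells, where clusters 10 and 13 had 0.14 and -0.24. MHC class I genes had a median of 0.32 [0.23 to 0.38], percentile 99.7, with B2m at 1.32 [1.28 to 1.35] and H2-K1 at 1.29 [1.23 to 1.34]. MHC class II genes had -0.40 [-0.45 to -0.36], percentile 0.01. The MHC medians are given over macrophage-like and monocyte-like cells together only, and the mix of these classes differs between the libraries. The proliferation list was lower in 11 of 11 members, at -0.73 [-0.90 to -0.58], percentile 0. Mki67 was at 0.432 [0.366 to 0.510] and Top2a at 0.582 [0.487 to 0.695]. Taken apart, the log2 ratio of Mki67 was -0.79 in macrophage-like and 0.77 in monocyte-like cells, and that of Top2a -0.31 in macrophage-like and -0.22 in monocyte-like cells. Proliferating macrophage-like cluster 29 held 24, 24, 25 and 25 cells in the vehicle, panobinostat, givinostat and ruxolitinib libraries, while monocyte-like cells were more numerous in each drug library. Taken apart, the proliferation median was -0.31 in macrophage-like cells, and too few members were measured in monocyte-like cells for a median. The givinostat library is the deepest and lies on the other side of the retrocopy split from vehicle. Tpm3-rs7, from that split, was its highest gene in these cells (12.3 [7.77 to 20.5]).

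The givinostat library held 175 macrophage-like and 299 monocyte-like cells against 151 and 149 in the vehicle library. Within monocyte-like cells Ly6c2 was at 370 CPM in the vehicle library and 632 CPM in the givinostat library, and the lectin Clec4e had a log2 ratio of 1.12. Over both classes Cyp4f18, an eicosanoid hydroxylase, was at 2.90 [2.31 to 3.66] and the interferon-inducible Ifi209 at 2.12 [1.76 to 2.59]. Mmp12 was at 0.181 [0.158 to 0.205] and Pf4 at 0.301 [0.253 to 0.357] times vehicle. Trem2, a lipid receptor of tissue macrophages, was at 0.454 [0.386 to 0.534], the tetraspanin Cd63 at 0.488 [0.444 to 0.537] and the flippase Atp11b at 0.428 [0.382 to 0.481] times vehicle. The counts of Cd63, at 1191 CPM in proximal tubule-like cells of the vehicle library, include RNA of tubule cells. Taken apart, the log2 ratio of Mmp12 was -1.96 in macrophage-like and 0.36 in monocyte-like cells, that of Cd63 -0.68 in macrophage-like and -1.04 in monocyte-like cells, that of Atp11b -0.27 in macrophage-like and -1.65 in monocyte-like cells and that of Clec4e -0.14 in macrophage-like and 1.12 in monocyte-like cells. That of Cyp4f18 was 3.08 in macrophage-like and 0.79 in monocyte-like cells, that of Ifi209 0.70 in macrophage-like and 1.22 in monocyte-like cells, that of Pf4 -1.23 in macrophage-like and 0.05 in monocyte-like cells and that of Trem2 -1.001 in macrophage-like and -0.40 in monocyte-like cells.

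**Figure D3:**
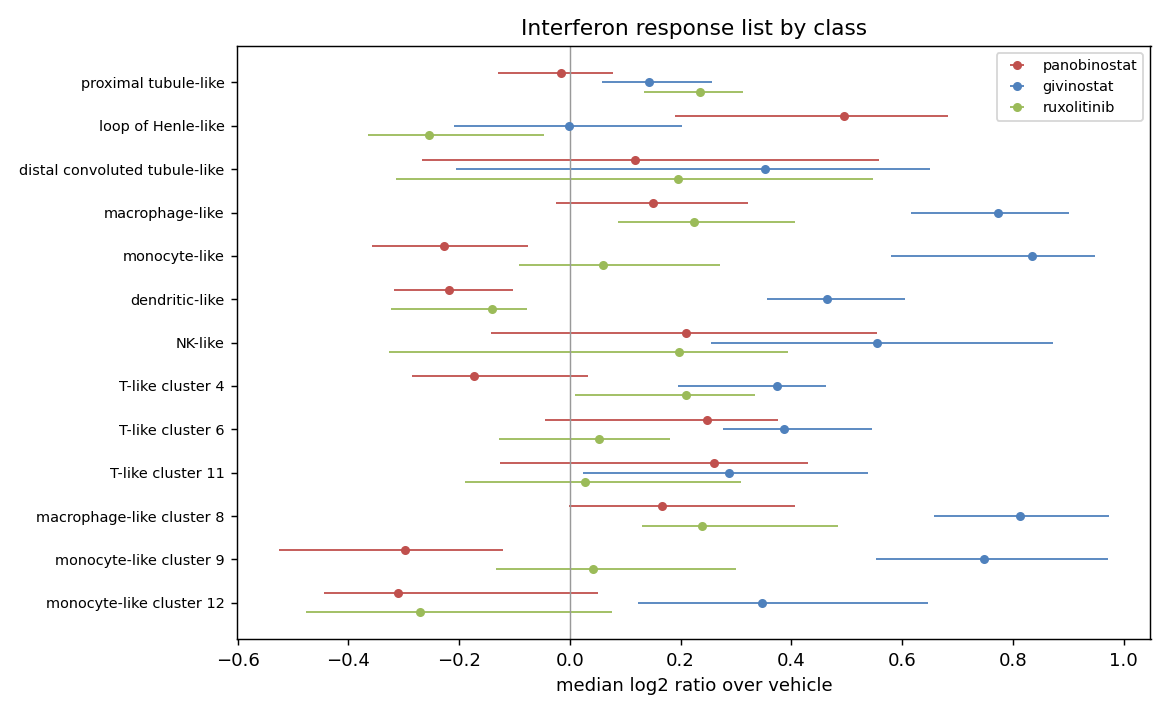
Median log2 ratio over vehicle of the interferon response list in each class or cluster with at least 50 cells per library, by drug, with 95% intervals from Poisson redraws. The givinostat medians of macrophage-like (0.77) and monocyte-like cells (0.83) lie to the right of the panobinostat medians (0.15 and -0.23).

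In proximal tubule-like cells of the ruxolitinib library, the lipid carrier Apoe was at 97.4 and 283 CPM in the vehicle and ruxolitinib libraries (2.91 [2.77 to 3.06] times vehicle; chromosome 7, 19696109 to 19699188) and the repressor Bcl6 at 106 and 30.2 CPM (0.286 [0.262 to 0.313]; chromosome 16, 23965052 to 23988852). Apoe is also among the genes that mark macrophage-like cluster 8, and RNA of leukocytes was not excluded for it. Id3, an inhibitor of helix-loop-helix factors, was at 2.29 [2.16 to 2.44], and the endoplasmic reticulum proteins Manf and Hspa5 were at 1.96 [1.84 to 2.08] and 1.77 [1.73 to 1.81]. The fibrinogen chain Fgg and Gsta2 were at 1.77 [1.66 to 1.89] and 1.71 [1.64 to 1.78]. Mogat1 was at 218 and 92.1 CPM in the vehicle and ruxolitinib libraries. Cyp4a14, Angptl4, Ier2 and the interferon-inducible Ly6e were at 0.458 [0.428 to 0.490], 0.496 [0.473 to 0.519], 0.505 [0.469 to 0.544] and 0.525 [0.502 to 0.548]. In the list of JAK-STAT feedback genes and STAT3 targets, 7 of 9 members were above vehicle with a median of 0.19 [0.13 to 0.31], percentile 87.4. It was 0.0794 with TMM and 0.0806 with DESeq2 scaling, and 0.46 among members with at least 50 CPM. Socs2 was at 1.15 [1.05 to 1.26] and the immediate early gene Junb at 0.602 [0.573 to 0.632]. Cish, a feedback inhibitor of cytokine receptors, chosen after its values were seen, was at 3.09 and 35.7 CPM (11.6 [8.97 to 15.1]), against 0.953 [0.668 to 1.36] and 0.608 [0.391 to 0.931] in the panobinostat and givinostat libraries.

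Transport genes were higher in the ruxolitinib library in 13 of 17 members, at 0.22 [0.16 to 0.24], percentile 100, among them Lrp2 at 1.17 [1.15 to 1.19], while Slc34a1 was at 0.892 [0.884 to 0.900]. TMM and DESeq2 scaling shift the median of all genes in these cells by -0.11 and -0.11, and with TMM the transport median is 0.11. The tubular injury list had a median of -0.35 [-0.44 to -0.27], percentile 0.04, with Krt8 at 0.621 [0.591 to 0.652] and Spp1 at 1.07 [1.06 to 1.08]. With no filter on members, a setting that draws medians toward 0, the injury median was -0.0293, within counting error of no change. Genes known to rise with deacetylase inhibition had -0.55 [-0.60 to -0.43], percentile 0, and the fatty acid oxidation list was lower in 13 of 15 members, at -0.16 [-0.19 to -0.13], percentile 0.03. These medians, that of tubular injury and the ratio of Krt8 are pooled over clusters, so the cluster mix may enter them. The stress and immediate early list had -0.20 [-0.23 to -0.17], percentile 0 over all proximal tubule-like cells and 0.13, -0.12, -0.02, 0.14 and 0.29 within clusters 0, 1, 2, 3 and 5. In the same clusters the transport median was 0.00, -0.03, 0.13, -0.19 and 0.12. The pooled transport value therefore moved with the cluster mix. The log2 ratio of Bcl6 was -1.37, -1.54, -1.66, -1.12 and -1.81, that of Apoe 1.74, 0.23, 2.14, 0.87 and 1.87 and that of Cish 1.27, 2.23, 2.64, 1.20 and 3.05.

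In macrophage-like and monocyte-like cells of the ruxolitinib library, Mmp12 was at 0.267 [0.234 to 0.304] and Fabp5 at 0.317 [0.273 to 0.368] times vehicle. Mmp12 was below vehicle in every drug library, and these ratios share the vehicle library. Taken apart, the log2 ratio of Mmp12 was -1.71 in macrophage-like and 0.00 in monocyte-like cells, that of Atp11b 0.63 in macrophage-like and -1.81 in monocyte-like cells, that of Thbs1 -0.51 in macrophage-like and 0.68 in monocyte-like cells and that of Ccl12 0.93 in macrophage-like and 0.98 in monocyte-like cells. That of Fabp5 was -2.59 in macrophage-like and -0.25 in monocyte-like cells, that of Cd63 -0.92 in macrophage-like and -1.21 in monocyte-like cells, that of Hpgd 0.50 in macrophage-like and 0.79 in monocyte-like cells, that of Fgd4 0.19 in macrophage-like and 0.74 in monocyte-like cells and that of Tppp3 -0.13 in macrophage-like and 0.48 in monocyte-like cells. Cd63 and Atp11b were at 0.465 [0.417 to 0.518] and 0.439 [0.386 to 0.4997]. Cd63 was at 346 and 161 CPM in these cells and 1191 and 1129 CPM in proximal tubule-like cells, so its counts include RNA of tubule cells. Acy3 and Cyp4b1, at 0.407 [0.351 to 0.472] and 0.431 [0.376 to 0.493], are abundant in proximal tubule-like cells of the vehicle library (1575 and 1514 CPM). Their log2 ratios were -0.39 in macrophage-like and -2.16 in monocyte-like cells and -0.23 in macrophage-like and -2.14 in monocyte-like cells. The chemokine Ccl12 was at 109 and 189 CPM in the vehicle and ruxolitinib libraries. The matrix protein Thbs1 was at 1.68 [1.42 to 1.99], the prostaglandin dehydrogenase Hpgd at 1.61 [1.42 to 1.82], Fgd4 at 1.62 [1.35 to 1.96] and Tppp3 at 1.54 [1.34 to 1.76]. Tpm3-rs7, from the retrocopy split, was at 15.2 [9.61 to 25.4]. The interferon response list had 14 of 24 members above vehicle and a median of 0.19 [0.05 to 0.32], percentile 98.8, with Irf7 at 0.652 [0.547 to 0.777] and Bst2 at 0.806 [0.694 to 0.937]. Cxcl10, chosen after its values were seen, was at 2.31 [1.80 to 2.98]. The JAK-STAT feedback list had 0.10 [0.04 to 0.25], percentile 79.3, with Socs3 at 1.04 [0.957 to 1.13], and turned to -0.00566 in thinned cells. The proliferation list had -0.72 [-0.78 to -0.38], percentile 0, with Top2a at 0.552 [0.452 to 0.673]. Taken apart, the proliferation median was -0.58 in macrophage-like cells of the ruxolitinib library.

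**Figure D4:**
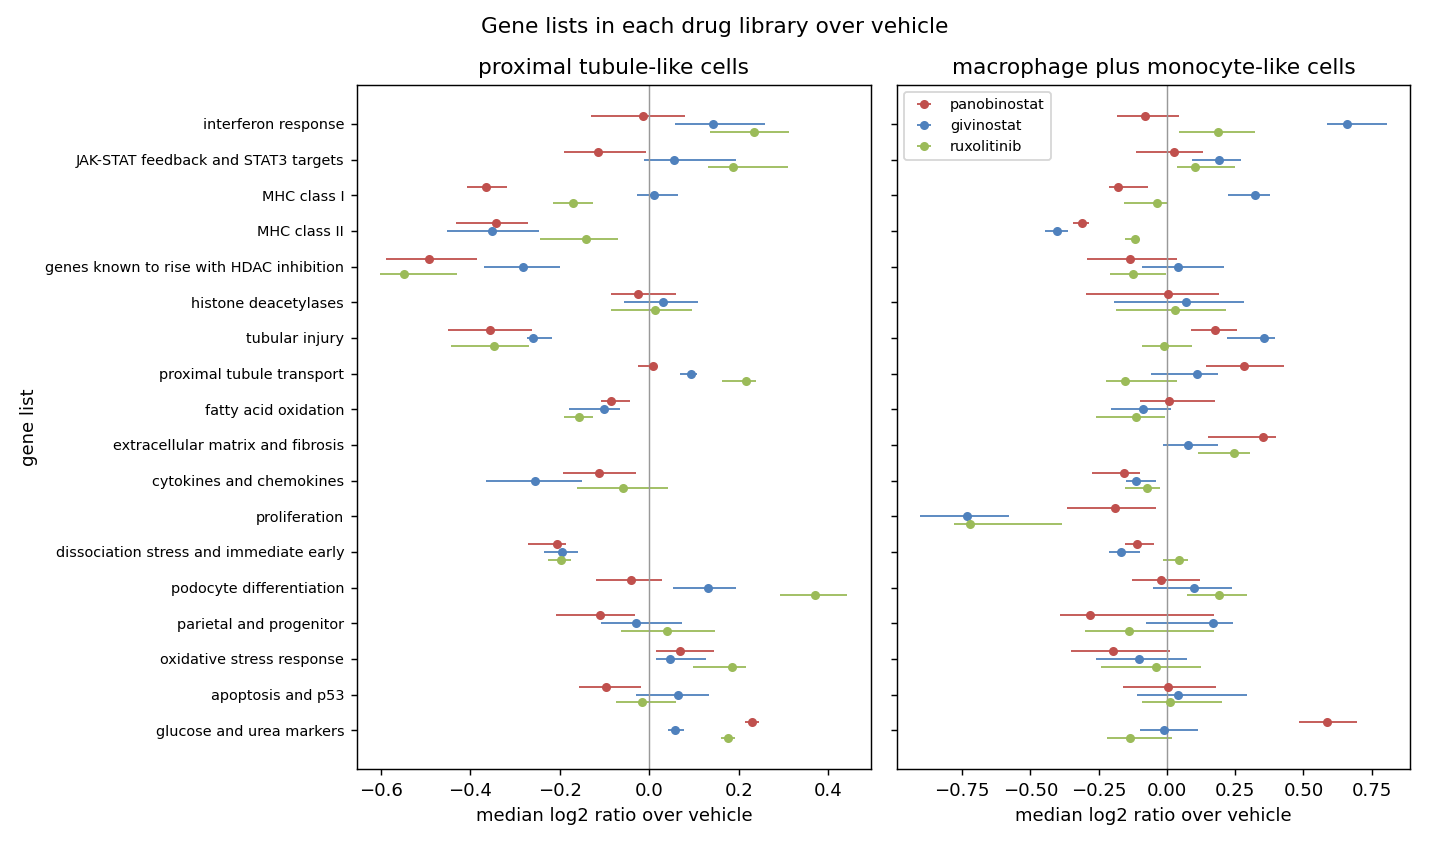
Median log2 ratio over vehicle of each gene list in proximal tubule-like cells (left) and in macrophage-like plus monocyte-like cells (right), by drug, with 95% intervals from Poisson redraws. The interferon response list in macrophage-like plus monocyte-like cells is at -0.08, 0.66 and 0.19 in the panobinostat, givinostat and ruxolitinib libraries.

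Panobinostat and givinostat are both hydroxamate inhibitors of histone deacetylases, given here at different doses, 15 and 10 mg/kg, for the same days. In macrophage-like and monocyte-like cells 0 of 24 interferon genes were higher in the panobinostat than in the givinostat library, with a median log2 ratio of -0.75 [-0.91 to -0.70], percentile 0. Irf7 was at 82.5 and 156 CPM and Cxcl10 at 32.4 and 92.3 CPM in the panobinostat and givinostat libraries (Cxcl10 was chosen after its values were seen). MHC class I genes had -0.44 [-0.48 to -0.35], percentile 0.01 in these cells and -0.38 [-0.42 to -0.33], percentile 0.42 in proximal tubule-like cells, where H2-K1 was at 89.3 and 143 CPM. In the proximal tubule-like cells RNA of leukocytes was not excluded. The proliferation list in macrophage-like and monocyte-like cells had 0.48 [0.38 to 0.66], percentile 100, with Mki67 at 99.4 and 54.0 CPM. Genes known to rise with deacetylase inhibition had -0.23 [-0.28 to -0.19], percentile 7.32 in proximal tubule-like cells. The transport list had -0.08 [-0.08 to -0.05], percentile 8.77. TMM shifts of 0.00 (panobinostat) and -0.09 (givinostat) over vehicle are as large as this transport difference. These libraries differ in depth and lie on opposite sides of the retrocopy split, and their difference was described and not tested.

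In proximal tubule-like cells the oxidative stress response list had medians of 0.07, 0.05 and 0.18 in the panobinostat, givinostat and ruxolitinib libraries. The givinostat value turned to -0.0389 with TMM, -0.0482 with DESeq2 scaling and -0.00898 in thinned cells. The apoptosis and p53 list had -0.10, 0.06 and -0.02, and the parietal and progenitor list -0.11, -0.03 and 0.04. The podocyte differentiation list, of which 4 members were measured in these cells, Actn4 and Cd2ap among them, had -0.04, 0.13 and 0.37. In macrophage-like and monocyte-like cells the extracellular matrix and fibrosis list had 0.35, 0.08 and 0.24, and the ruxolitinib value turned to -0.0370 in thinned cells. These values are given over both classes only, whose mix differs between the libraries. The podocyte-like share was 0.382% [0.214 to 0.629] in the vehicle library and 0.114% [0.0369 to 0.265], 0.374% [0.1995 to 0.639] and 0.352% [0.193 to 0.590] in the panobinostat, givinostat and ruxolitinib libraries.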

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

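Both tests in this part were chosen after the result was seen. The Confetti reporter transcripts are not used in the comparisons, and over all kept cells some stood above vehicle in the givinostat and ruxolitinib libraries and none in the panobinostat library. The nuclear green reporter hrGFPIINLS was at 1.60 [1.40 to 1.83] and 1.94 [1.70 to 2.21] times vehicle in the givinostat and ruxolitinib libraries, on 338, 110, 599 and 691 UMIs in the vehicle, panobinostat, givinostat and ruxolitinib libraries. The yellow reporter EYFP was at 2.86 [2.08 to 4.003] and 2.25 [1.61 to 3.18], and the red reporter tdimer2 at 2.54 [2.02 to 3.21] and 1.97 [1.55 to 2.52], in the same libraries. The membrane cyan reporter MbmCerulean was at 3.43 [2.71 to 4.38] in the ruxolitinib library and 1.26 [0.955 to 1.67] in the givinostat library. By class the ratios differ: hrGFPIINLS in the ruxolitinib library was at 1.01 [0.798 to 1.27] in loop of Henle-like cells and 5.73 [4.18 to 7.97] in collecting duct principal or connecting tubule-like cells. In intercalated-like cells of the givinostat library MbmCerulean was at 0.471 [0.257 to 0.843] and EYFP at 0.229 [0.0232 to 1.20], the latter on 2 against 7 UMIs. The pooled values therefore mix classes whose shares differ between libraries. In the panobinostat library hrGFPIINLS, EYFP, tdimer2 and MbmCerulean were at 0.359 [0.287 to 0.446], 0.562 [0.336 to 0.918], 0.342 [0.223 to 0.513] and 0.882 [0.638 to 1.22] times vehicle. The givinostat and ruxolitinib libraries also stand together in the retrocopy split.

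The split of vehicle and panobinostat from givinostat and ruxolitinib rests on 7 genes, and 100% of them are RefSeq pseudogenes against 0.207% of the genes tested. They lie on 4 chromosomes, which argues against one linked stretch of the genome that differs between the animals. The share of pseudogenes depends on the annotation: GENCODE gives 2 of the 7 as pseudogenes (Gm10036 and Rpl27-ps3), 4 as protein-coding (Tpm3-rs7, Gm2000, Rpl9-ps6 and Rps12-ps3) and Gm10076 as a long noncoding RNA. A difference between library or sequencing batches that moves reads among retrocopies and their parent genes therefore stays open, and the labels give no batch. Tpm3, the parent of Tpm3-rs7, was at 172, 151, 200 and 148 CPM in the vehicle, panobinostat, givinostat and ruxolitinib libraries. Apart from the linked stretch no biological explanation was tested, and unlinked differences between the animals stay open.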

How the results depend on the processing

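The common floor, the common fraction of the proximal tubule-like median, the highest 6% of doublet scores, the reduced denominator, clustering without list members and the list settings of DESeq2, pseudocount, doublets and thinning were chosen after seeing the data, and the other alternatives before the data were examined. Within counting error of the value in the report were 128 of 144 values of shares, 195 of 240 of the lists followed as main results, and 565 of 654 of other lists. Of the values of named genes 375 were within it and 129 moved beyond it. No named gene changed direction, but these genes were named for the highest or lowest log2 ratios. A pseudocount leaves the sign of a ratio as it is. TMM shifted log2 ratios in proximal tubule-like cells of the ruxolitinib library by -0.11, against 0.76 for Gsta2. These alternatives therefore tested direction only weakly. Classes taken apart were not among them. In the panobinostat library Mmp12 was then at -1.10 in macrophage-like and 0.45 in monocyte-like cells, and Clec4n at -1.73 and -1.01. The lists followed as main results are immediate early, transport, tubular injury, HDAC-rise and JAK-STAT in proximal tubule-like cells and interferon, MHC class II, HDAC-rise and JAK-STAT in macrophage-like plus monocyte-like cells. Alternatives for the matrix without a map from cells to samples were not run, since cells map to samples. Cell by cell classes give no value for numbered T-like clusters, and no replicate was left out, since each group has 1 library. No paired analysis was possible because the labels pair no animals. Below, shares are folds and lists median log2 ratios over vehicle in proximal tubule-like cells, or, where marked myeloid, in macrophage-like plus monocyte-like cells. Reversed marks a change of sign of a value whose interval under the main settings excludes 0 (1 for shares). The main values of JAK-STAT (panobinostat) and of glucose and urea (givinostat) are not reported here and had the opposite sign. The cause was not tested.

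With the stricter cell filter, proximal tubule-like share was 1.37 (panobinostat) and Ctla4 and Cd4 T-like share was 0.701 (panobinostat), 2.01 (givinostat) and 0.834 (ruxolitinib). At Leiden resolution 1.5, Ctla4 and Cd4 T-like share was 0.665 (panobinostat), 2.20 (givinostat) and 0.777 (ruxolitinib). With the common UMI floor of 5272, proximal tubule-like share was 0.651 (givinostat) and leukocyte-like share was 1.89 (givinostat) and 1.22 (ruxolitinib). Il17a and Trdc T-like share was 0.116 (panobinostat), 4.99 (givinostat) and 2.25 (ruxolitinib) and Ctla4 and Cd4 T-like share was 0.253 (panobinostat), 3.50 (givinostat) and 1.04 (ruxolitinib, reversed). With no member filter, JAK-STAT was 0.00485 (panobinostat, reversed) and HDAC-rise was -0.38 (panobinostat) and -0.13 (givinostat). Tubular injury was -0.0587 (panobinostat), 0.0131 (givinostat, reversed) and -0.0293 (ruxolitinib). With members at 50 CPM or more, immediate early was -0.34 (panobinostat) and HDAC-rise was -0.14 (givinostat) and -0.24 (ruxolitinib). JAK-STAT was 0.46 (ruxolitinib). With a 20 CPM pseudocount, HDAC-rise was -0.31 (panobinostat) and -0.33 (ruxolitinib) and tubular injury was -0.20 (ruxolitinib). Interferon was 0.52 (givinostat) in myeloid cells. With a 1 CPM pseudocount, HDAC-rise was -0.60 (ruxolitinib). With TMM totals, JAK-STAT was -0.0237 (givinostat) and 0.0794 (ruxolitinib) and tubular injury was -0.35 (givinostat). Transport was -0.00237 (givinostat, reversed) and 0.11 (ruxolitinib) and immediate early was -0.29 (givinostat) and -0.30 (ruxolitinib). Oxidative stress was -0.0389 (givinostat, reversed) and glucose and urea was -0.0366 (givinostat, reversed). HDAC-rise was -0.64 (ruxolitinib). With DESeq2 size factors, JAK-STAT was -0.0322 (givinostat) and 0.0806 (ruxolitinib) and HDAC-rise was -0.38 (givinostat) and -0.64 (ruxolitinib). Tubular injury was -0.37 (givinostat) and transport was -0.0137 (givinostat, reversed) and 0.11 (ruxolitinib). Immediate early was -0.30 (givinostat) and -0.30 (ruxolitinib) and oxidative stress was -0.0482 (givinostat, reversed). Glucose and urea was -0.0480 (givinostat, reversed). In thinned cells, transport was -0.0578 (panobinostat) and 0.13 (ruxolitinib) and immediate early was -0.38 (panobinostat) and -0.29 (givinostat). JAK-STAT was -0.0883 (givinostat) and tubular injury was -0.15 (givinostat). Oxidative stress was -0.00898 (givinostat, reversed) and MHC class II was -0.43 (panobinostat) and -0.20 (ruxolitinib) in myeloid cells. Interferon was 0.57 (givinostat) in myeloid cells and JAK-STAT was -0.00566 (ruxolitinib, reversed) in myeloid cells. Matrix was -0.0370 (ruxolitinib, reversed) in myeloid cells. Without the highest 6% of doublet scores, MHC class II was -0.35 (panobinostat) and -0.19 (ruxolitinib) in myeloid cells. Without Scrublet doublets, MHC class II was -0.33 (givinostat) in myeloid cells.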

Other observations

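The tests of the Il17a and Trdc cluster against other clusters and general loss, and those of interferon against the split and the cluster mix, were chosen after the result was seen. All genes of this paragraph were chosen after their values were seen. In T-like cluster 4 the cytotoxic protease gene Gzmb was at 76.3 CPM in the vehicle library and at 1.84 [1.43 to 2.38], 5.49 [4.51 to 6.74] and 6.28 [5.12 to 7.77] times that in the panobinostat, givinostat and ruxolitinib libraries. The larger ratios fell in the givinostat and ruxolitinib libraries, which stand together in the retrocopy split. The drugs cannot be told apart from that split here. At Leiden resolution 1.5 T-like cluster 4 separates into a Cd8a and Cd8b1 cluster and an unnamed one led by Xcl1, Klra5 and Trdc. Gzmb was at 1.60 [1.11 to 2.31], 4.62 [3.47 to 6.26] and 6.47 [4.83 to 8.82] times vehicle in the first and 2.03 [1.43 to 2.91], 6.36 [4.84 to 8.50] and 5.51 [4.11 to 7.48] in the second. T-like cluster 6 separates there into a Ctla4 and Cd4 cluster and an Il17f and Il17a cluster, which held 156, 16, 72 and 54 cells in the vehicle, panobinostat, givinostat and ruxolitinib libraries. In the latter Il17a was at 0.837 [0.751 to 0.932] and 1.48 [1.32 to 1.65] times its vehicle level of 1131 CPM in the givinostat and ruxolitinib libraries, and the panobinostat library held too few cells for a level. Over the whole of cluster 6 it was at 0.144 [0.103 to 0.198], 0.368 [0.331 to 0.410] and 0.945 [0.848 to 1.05], so the pooled values mix cell numbers with levels.

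The classes and genes of this paragraph were also chosen after their values were seen. In distal convoluted tubule-like cells the stress and immediate early list had a median of -0.93 [-1.15 to -0.80], percentile 0 in the ruxolitinib library and 0.33 [0.23 to 0.41], percentile 100 in the panobinostat library, with Fos at 0.186 [0.151 to 0.227] and 1.26 [1.15 to 1.39] times vehicle. In collecting duct principal or connecting tubule-like cells 14 of 14 members were higher in the panobinostat library, at 0.87 [0.76 to 0.98], percentile 100. In loop of Henle-like cells the tubular injury list had medians of 0.32, 0.24 and 0.27 in the panobinostat, givinostat and ruxolitinib libraries, with Spp1 at 1.251 [1.23 to 1.27], 1.36 [1.34 to 1.37] and 1.60 [1.59 to 1.62]. The class mixes cluster 10 (175, 104, 107 and 161 cells in the vehicle, panobinostat, givinostat and ruxolitinib libraries) and cluster 13, led by Igfbp2 and Lcn2 (80, 63, 82 and 131 cells). Taken apart, the injury medians were 0.03 [-0.08 to 0.18], -0.15 [-0.37 to 0.02] and 0.16 [0.00 to 0.29] in cluster 10 and 0.24 [-0.11 to 0.28], 0.14 [-0.03 to 0.27] and 0.03 [-0.45 to 0.15] in cluster 13, none with an interval clear of 0. Spp1 was at 0.994, 1.02 and 1.24 and 1.18, 1.21 and 1.36 times vehicle. The pooled injury values therefore rest in good part on the cluster mix. The interferon response list in loop of Henle-like cells of the panobinostat library had 0.49 [0.19 to 0.68], percentile 100, with 0.37 [0.18 to 0.69] in cluster 10 and 0.32 [-0.09 to 0.51] in cluster 13. In the givinostat library it had 0.00 [-0.21 to 0.20], percentile 22.9, with 0.14 [-0.23 to 0.28] and -0.24 [-0.46 to 0.05]. In the ruxolitinib library it had -0.25 [-0.37 to -0.05], percentile 0.04, with -0.28 [-0.71 to 0.01] and -0.34 [-0.61 to -0.12]. Erythroid-like cells numbered 5, 97, 70 and 138 in the vehicle, panobinostat, givinostat and ruxolitinib libraries. The filter of 200 genes had left out 0, 109, 2 and 115 more cells, whose UMIs in the last 3 libraries were 91.5%, 92.4% and 93.4% haemoglobin. NK-like cells made up 1.40%, 2.43%, 2.77% and 1.66%.

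The T-like cluster of Il17a and Trdc was smaller in the panobinostat library, and over the whole library Il17a was at 0.112 [0.0976 to 0.127] and Trdc at 0.420 [0.376 to 0.468] times vehicle. Held to the same fraction of each proximal tubule-like median, the cluster's share was at 0.235 times vehicle [0.143 to 0.372]. The vehicle and panobinostat floors already stood at 0.381 and 0.380 of those medians. This setting could therefore hardly move the ratio, and different UMI floors and depths stay open. Its fold among all T-like cells was 0.407 [0.259 to 0.619], which argues against a general loss of T-like cells as the whole cause. Trdc per UMI of all T-like and unnamed clusters was at 0.687 [0.613 to 0.770], between the bounds set, so cells placed in other clusters stay open in part. T-like cells were themselves at 0.531 times their vehicle share, so this ratio is not on the scale of the whole-library ones. The whole-library ratios do not depend on how cells were clustered, so placement in other clusters alone does not account for them. A lower number of Il17a-bearing T-like cells after panobinostat is a hypothesis that 1 library per group cannot separate from a difference between animals.

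The interferon response list was higher in macrophage-like plus monocyte-like cells of the givinostat library. In cells thinned to the same UMI number its median was 0.57 [0.40 to 0.72]. Thinning keeps the mix of transcripts within each cell and the same cells above each floor. It therefore cannot decide on the higher depth, which stays open. The ruxolitinib median was 0.19 [0.05 to 0.32]. Ruxolitinib inhibits the kinases that carry interferon signals, so this leaves open the split that givinostat shares with ruxolitinib. The lowest median over clusters 8, 9 and 12 was 0.35 [0.12 to 0.65], in cluster 12, and the median without the 5% of cells with the highest interferon share was 0.47 [0.34 to 0.55], so a mix of clusters and a few very high cells stay open for part of it. A response to givinostat may account for some of it, as a hypothesis, and a difference between the animals stays open and untested.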
